A study of Caenorhabditis elegans with 23 samples.

How the data were processed

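Messenger RNA and small RNA of whole Caenorhabditis elegans were counted per gene in 23 libraries: 12 of mRNA, 3 from each of 4 groups, and 11 of small RNA. The groups were N2, the reference laboratory strain, MY16, a wild isolate, and N2_Star and MY16_Star, whose added word the labels do not explain. The worms were adults of day 1 kept at 20 °C on E. coli OP-50, and RNA was extracted from whole animals with TRIzol, per the labels' protocols. The design text says that an MY16_Star small RNA library failed, whereas the sample list and the table columns hold 3 MY16_Star and 2 N2_Star libraries. The groups used here follow the sample list and the columns. The design text calls the replicates biological, and nothing further states how they were kept apart.

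The values are whole-number counts of reads per gene as the authors deposited them, with no normalization. Per the submitters' processing notes, reads were trimmed with cutadapt, checked with FastQC, aligned to ce11 with Bowtie2 and counted with HTSeq, and groups were compared with DESeq2; no versions or annotation release were given. The labels' protocols name a small RNA library kit for both assays, and whether the counting used strand is not stated. In mRNA, it is therefore not known whether reads from a gene and an antisense neighbour were told apart. The name of the deposited small RNA table carries the letters AS, which no label defines and which may stand for antisense. This was checked on the values after they were seen. Of 214 miRNA genes, whose own strand makes the mature small RNA, 209 had a mean under 1 CPM, and 15339 piRNA genes together took 0.0886% to 0.193% of the gene counts. The noncoding RNA genes T09B4.14, F16A11.6 and K01F9.6, which overlap mir-1, mir-71 and mir-80, had means over all libraries of 45769, 28290 and 13107 CPM, against 0.0254, 0.19 and 0.835 for the miRNA genes. They are the most abundant of 42 overlapping pairs, in which the partner was higher in 35 and the miRNA gene in 6. Counting without strand would have set reads in such overlaps aside as ambiguous, and those made up 0.217% to 0.308% of a library. The small RNA values thus fit reads counted on the strand opposite to the gene, and small RNA of a gene is read here as antisense to it. In mRNA ambiguous reads made up 0.116% to 0.145% of a library, so strand may have been used there as well; which strand was not checked. Genes with near-identical copies, such as the msp, histone, fbx, bath and pals families, may share reads, and their values are uncertain to that extent. The RNA of MY16 was aligned to the genome of N2, so a gene that is diverged or missing in MY16 can have fewer counts at the same RNA level.

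The tables held 46904 gene IDs, of which 44017 matched a symbol in the RefSeq annotation of WBcel235, the assembly that ce11 names; coordinates are 1-based and come from that annotation. Summary lines that name no gene were kept out of library sizes and tests. They took 7.84% to 17.7% of the mRNA counts and 38.7% to 46.6% of the small RNA counts. In small RNA, reads that the counting placed in no gene feature took 24.8% to 36.7% and reads not aligned took 9.14% to 14.9%. If only the strand opposite to a gene was counted, the former also hold reads on a gene's own strand. Gene counts ranged from 9362590 to 23150198 per mRNA library and from 1778321 to 19563562 per small RNA library. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to 0.127 to 0.311 CPM in mRNA and 0.134 to 1.95 CPM in small RNA. Such floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

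Each assay was fitted once over its 4 groups with edgeR 4.0.16 under R 4.3.3, with limma 3.58.1. Library sizes were scaled by TMM, genes were filtered with filterByExpr (13983 mRNA and 12241 small RNA genes stayed), and contrasts were tested with the quasi-likelihood F-test (glmQLFit, glmQLFTest). Adjusted p-values are Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05, and the standard error of a log2 fold change is its size divided by the square root of F. The contrasts were MY16 against N2, each Star group against the isolate it is named after, MY16_Star against N2_Star, and the interaction, which is the MY16_Star minus MY16 difference less the N2_Star minus N2 difference. CPM values are TMM-scaled and given as mean ± SD over libraries. A fold against a group with 0 counts in all its libraries was computed against 3 counts in each of its libraries and is a lower bound.

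The following choices were made before the data were examined: the groups, the contrasts, the tests, the alternatives, the gene lists and the rule for naming genes. The rule took, per contrast, the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold with a mean of at least 5 CPM and libraries that did not overlap between the groups; the 4 members of each list with the smallest p; and gpr-1, peel-1, zeel-1, sup-35, pha-1, hrde-1, prg-1, sid-1, ppw-1 and rde-1 always. The 24 lists held 2755 genes: spermatogenesis, oocyte and maternal germline, early embryo zygotic genes, vitellogenins, collagens, intestine, body wall muscle, neurons, Argonautes, RNAi and small RNA cofactors, ERGO-1 26G targets, WAGO and heritable silencing targets, replicative histones, ribosomal proteins, mitochondrial genome genes, spindle pulling force, toxin-antidote elements, F-box genes, MATH and BTB genes, C-type lectins, pals genes and intracellular pathogen response, chemoreceptors, heat shock and stress, and detoxification. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Lists with under 3 tested members had no test.

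The position of a library on the line from its own isolate (0) to the other isolate (1) was computed from log2 CPM with a prior count of 2. It used genes with a mean log2 CPM over 2 that differed by at least 1 log2 unit between the isolates. The isolate centre was always taken with 1 library left out, and Star and isolate libraries were compared with an exact two-sided permutation test. With 3 against 3 libraries the smallest p is 0.1, and with 2 against 3 it is 0.2. Comparisons that share libraries were set beside 20 simulations of unchanged Star groups. Alternatives were DESeq2 size factors, library totals, no filter, the DESeq2 1.42.0 Wald test, the replicate number as a block, a fit of the compared groups alone, other gene filters for the position, and each library left out in turn. Adjusted p-values that DESeq2 gave as NA stayed NA. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

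The numbers given to replicates were checked for pairing from the correlation, across genes, of same-numbered libraries' deviations from their group means. Only MY16_Star and MY16 small RNA had every pair above 0.1, with r = 0.316, 0.117 and 0.364; this pairing comes from the data, as the labels name no shared batch or day. The tests were run first on simulated counts with known changes in MY16_Star against MY16. In mRNA, over 13655 tested genes, 43.3% of 67 genes changed 2-fold, 83.6% of 67 changed 4-fold and 93.9% of 66 changed 8-fold were recovered, with 9 false calls among 156. In small RNA, over 11819 tested genes, the shares were 25.4%, 80.6% and 89.4%, with 4 false calls among 134. The unchanged MY16 against N2 contrast of the simulation gave 0 calls in both assays with edgeR. Simulated positions of 0 and 0.3 came out as 0.000938 and 0.263 in mRNA and as -0.000773 and 0.299 in small RNA.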

Results

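Messenger RNA and small RNA were counted per gene in whole day 1 adults of 4 C. elegans groups: N2, MY16, N2_Star and MY16_Star. The series concerns whether small RNAs pass between generations apart from the nucleus, and the labels do not say what Star marks. The comparisons therefore asked how the isolates differ, how each Star group differs from the isolate whose name it carries, and whether a Star group lies nearer to the other isolate. The mRNA totals of replicates 1, 2 and 3 were 17216592, 20194076 and 9362590 counts in MY16, 19019774, 18149023 and 15838061 in MY16_Star, 16005895, 11797329 and 23150198 in N2, and 18500267, 17874435 and 19278753 in N2_Star. The small RNA totals were 1961627, 6443261 and 6478428 in MY16, 4818890, 14118178 and 5909386 in MY16_Star, and 15514520, 19563562 and 1778321 in N2. The N2_Star small RNA libraries, 2 in number, held 16809884 and 4268550 counts. Values below are mean CPM ± SD with n = 3 libraries per group, except n = 2 for N2_Star small RNA.

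**Figure D1:**
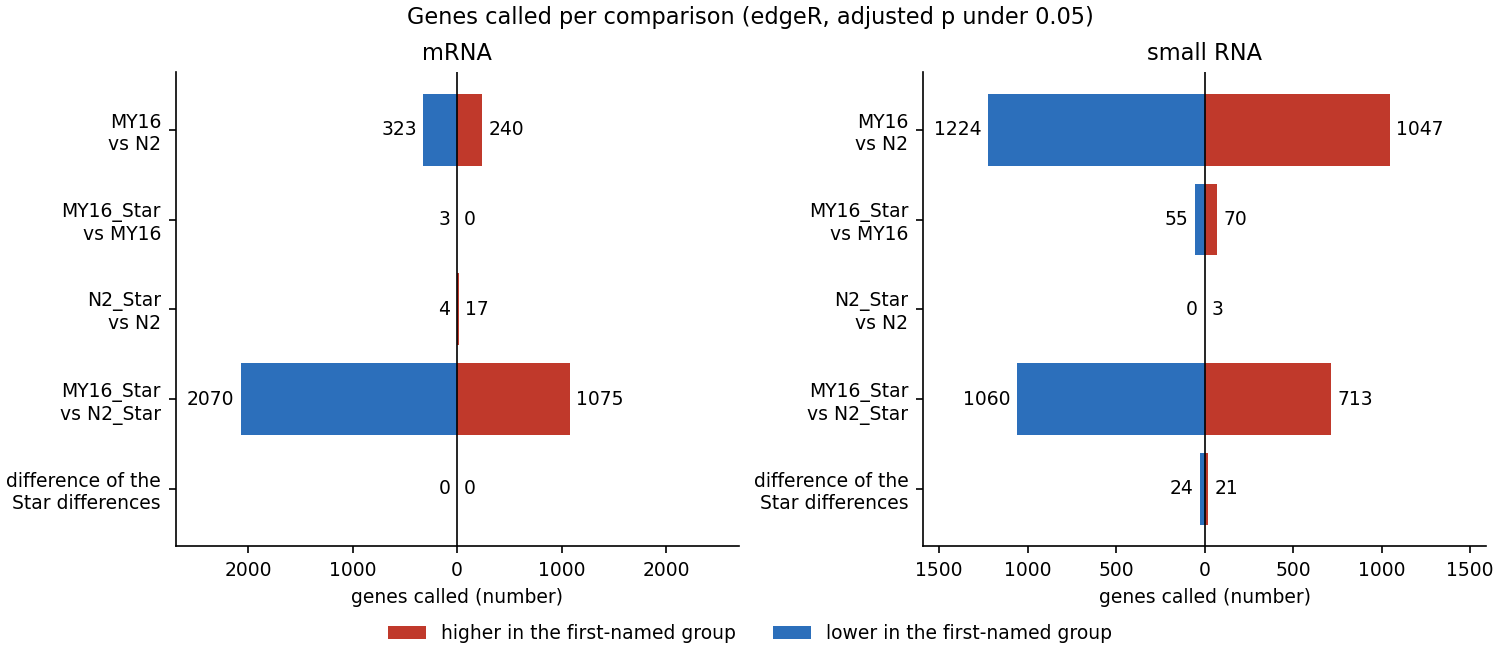
Number of genes called higher (bars to the right) and lower (bars to the left) in each comparison and assay by edgeR at an adjusted p under 0.05. The largest mRNA count, 3145, lies between the Star groups, and the largest small RNA count, 2271, between MY16 and N2.

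In mRNA, MY16 libraries held few or no counts at a set of genes that N2 worms expressed. Among them were genes of the MATH and BTB families, whose products include substrate adaptors of ubiquitin ligases. Reads were aligned to the N2 genome, so diverged or missing MY16 genes could give the same values as absent RNA. F52C6.2 (WBGene00018659, chromosome II, 1926462 to 1927347 in ce11) stood at 32.1 ± 2.05 CPM in N2 (SD, n = 3) and at 0 counts in every MY16 library, at least 152-fold lower. On the same chromosome, bath-5 (WBGene00019141) and bath-2 (WBGene00018668) were at least 143-fold and at least 113-fold lower, and sri-40, a predicted chemoreceptor gene, at least 115-fold lower. In the opposite direction, T10D4.1 (WBGene00020406) reached 18.7 ± 2.74 CPM in MY16 and 0 counts in every N2 library, at least 99.8-fold higher, and F55B11.5 stood at 51.2 ± 3.32 against 0.446 ± 0.216 CPM. All of these passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p of 8.51e-06 or less.

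Of the 61 MATH and BTB genes tested in mRNA, 18 were lower and 1 higher in MY16, or 23 lower and 7 higher adjusted over the list alone, with a median log2 fold change of -0.20. As single libraries were left out this median ran from -0.63 without MY16 replicate 3 to -0.08 without MY16 replicate 2. Camera gave an adjusted p of 2.94e-18 for this list, and adjusted p = 0.0243 with an estimated correlation. It was 1 of the 2 list calls, among 68 over all contrasts and both assays, that held with an estimated correlation. Among 75 spermatogenesis genes 4 were lower and 1 higher, or 7 and 1 adjusted over the list alone; msp-76, a major sperm protein gene, stood at 0.137 ± 0.119 CPM in MY16 and 24.1 ± 1.15 in N2, although its near-identical relatives may share its reads. The list had a camera adjusted p of 2.58e-10 and adjusted p = 0.804 with an estimated correlation. Replicative histones rose in 7 of 29 genes and fell in none, or in 8 adjusted over the list alone, among them his-64 from 1.60 ± 0.347 to 6.21 ± 1.21 CPM; the camera adjusted p was 0.000348, and adjusted p = 0.668 with an estimated correlation. F-box genes went both ways, with 12 of 139 higher and 11 lower (17 and 16 adjusted over the list alone), as did C-type lectins with 8 and 7 of 93 (12 and 11 alone), detoxification genes with 7 and 7 of 146 (10 and 7 alone) and chemoreceptors with 3 and 3 of 30 (4 and 4 alone). Among them cyp-35A4, a cytochrome P450 gene, rose from 4.24 ± 1.77 to 26.7 ± 3.85 CPM, and the C-type lectin gene clec-97 fell from 13.7 ± 0.913 to 0.597 ± 0.136; the camera adjusted p of these 4 lists was 0.635, 0.121, 0.163 and 0.434.

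The remaining lists had few called genes between MY16 and N2 in mRNA. E01G4.5, the single lower gene among 5 ERGO-1 26G targets, stood at 6.99 ± 0.656 CPM in N2 and 0 counts in MY16, at least 33.1-fold lower; adjusted over the list alone 1 was lower and 1 higher. Of 23 pals and pathogen response genes 1 was higher and 1 lower (2 and 1 adjusted over the list alone); the lower gene, skr-4, went from 14.2 ± 1.4 to 0.301 ± 0.106. The 8 WAGO and heritable silencing targets held 1 higher and 1 lower gene (2 and 1 alone), the 22 early embryo genes 2 lower, and Argonautes (20), intestine (15) and collagens (131) 1 higher each; these counts were the same adjusted over the list alone, except for the collagens with 0. The camera adjusted p of these lists was 0.19 or more. The medians of the F-box, early embryo, ERGO-1, WAGO, Argonaute and body wall muscle lists lay above 0 and their means below it. With edgeR, 0 members were called among oocyte and maternal germline genes (40), vitellogenins (6), body wall muscle (15), neurons (15), RNAi cofactors (51), ribosomal proteins (79), spindle pulling force (10), toxin-antidote elements (4) and heat shock genes (12). Mitochondrial genome genes had 0 tested members and no test. The genes hrde-1 and prg-1, which encode Argonautes of germline small RNA pathways, had log2 fold changes of 0.13 ± 0.169 (SE) and 0.04 ± 0.120, with edgeR adjusted p of 0.917 and 0.977. In all, 240 genes were higher and 323 lower in MY16 among 13983 tested, and 518 of the 563 differed more than 2-fold.

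Genes nearly without counts in an isolate, though abundant in the other, were also nearly without counts in the Star group of the same name. Of 13 genes above 10 CPM in every N2 library and at 3 counts or fewer in every MY16 library, all 13 stayed at 3 counts or fewer in every MY16_Star library, at no more than 0.160% of the N2 mean. These include bath-1, bath-2, bath-4, bath-5, bath-19 and sri-40; 7 of the 11 with a location lie on chromosome II. In N2_Star, each of the 13 stood at 75.3% of the N2 mean or more. Of the 2 genes with the opposite pattern, T10D4.1 and WBGene00194891, both stayed at 3 counts or fewer in N2_Star and stood at 106% of the MY16 mean or more in MY16_Star. At lower levels exceptions occur: pals-37 had 9.36 ± 4.54 CPM in MY16 and 0 counts in N2, but 0.938 ± 0.89 CPM in N2_Star (SD, n = 3; edgeR adjusted p 0.0836 against N2).

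MY16 libraries also held few or no small RNA counts at genes where N2 libraries held many, and the reverse. MATH and BTB and F-box genes lay on the lower side. The limit of aligning MY16 reads to the N2 genome holds here as well. Small RNA of bath-24 (WBGene00015014, chromosome II, 2044619 to 2045605 in ce11) stood at 246 ± 32.3 CPM in N2 (SD, n = 3) and 0 counts in MY16, at least 281-fold lower, and bath-20 (WBGene00015012) went from 4378 ± 1200 to 1.4 ± 1.77. F15D4.5, a heritable silencing target, fell from 4356 ± 733 to 2.64 ± 1.70 CPM. Higher in MY16 were nhr-113, a nuclear hormone receptor gene, at 43.1 ± 10.5 against 0.0149 ± 0.0258 CPM, inx-16, an innexin gene, at 126 ± 37.3 against 0.513 ± 0.686, and srh-25, a chemoreceptor gene, at least 21.1-fold. With edgeR each had an adjusted p of 3.28e-05 or less. Of 12241 genes, 1047 were higher and 1224 lower in MY16, and 1864 of the 2271 differed more than 2-fold.

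By list, 29 of 55 MATH and BTB genes had lower and 5 higher small RNA in MY16 (31 and 5 adjusted over the list alone; camera adjusted p 1.04e-12, and adjusted p = 0.116 with an estimated correlation). F-box genes had 60 lower and 19 higher of 180 (69 and 22 adjusted over the list alone; camera adjusted p 1.59e-06, and adjusted p = 0.636 with an estimated correlation), such as fbxb-97, which fell from 1072 ± 59.1 to 12.0 ± 2.43 CPM. The opposite change was seen for fbxb-119, which rose from 3.65 ± 0.525 to 136 ± 13.5. WAGO and heritable silencing targets had 6 lower of 12 (7 adjusted over the list alone; camera adjusted p 0.00285, and adjusted p = 0.636 with an estimated correlation). The lower genes include WBGene00017186 and WBGene00021107, whose near-equal means (62.0 and 66.0 CPM in MY16, 210 and 212 in N2) leave open that they share reads. Among other lists, C-type lectins were higher at 18 and lower at 6 of 55 (18 and 6 adjusted over the list alone), replicative histones lower at 17 and higher at 4 of 53 (20 and 5 alone), and chemoreceptors lower at 17 and higher at 8 of 62 (24 and 9 alone), with camera adjusted p of 0.0673, 0.101 and 0.101. Small RNA of nrde-2, a nuclear RNAi gene, fell from 526 ± 74.1 to 165 ± 36.1 CPM, and that of eri-3, a gene of an endogenous small RNA complex, rose from 92.0 ± 9.44 to 179 ± 31.7 (edgeR adjusted p 0.00017 and 0.00321).

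Genes that differed in small RNA between the isolates also differed in mRNA more often than independent lists would. Among 9864 genes tested in both assays, 122 were lower in both, where independent lists would share 19.8, and 40 were higher in both against 11.9. Reads that fail to align at diverged or missing MY16 genes would lower both assays alike. Genes with lower small RNA and higher mRNA numbered 30 against 12.5, and the reverse 21 against 18.9. E01G4.5 is an example of a gene lower in both, with a small RNA log2 fold change of -6.75 ± 0.784 (SE; edgeR adjusted p 7.84e-05). Across genes, which are not independent replicates, Spearman's rho was 0.10, and it was 0.0657 without genes at 3 counts or fewer in an isolate; those genes made up most of the shared lower set, which then held 40 genes against 9.64. Without them the other sets exceeded the counts of independent lists as well. There were 26 higher in both against 9.5, 29 with lower small RNA and higher mRNA against 9.02, and 21 the reverse against 10.2. Like and opposite directions were thus both in excess, so the overlap gives no single direction.

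MY16_Star worms carried small RNAs at a set of genes where N2 worms have them and MY16 worms nearly lack them. Small RNA of rcan-1 (WBGene00004321, chromosome III, 5682302 to 5684098 in ce11), a regulator of calcineurin, rose from 0.844 ± 0.316 CPM in MY16 to 75.2 ± 7.32 in MY16_Star (SD, n = 3), with 224 ± 45.7 in N2. That of zip-2 (WBGene00019327), a bZIP transcription factor gene of the pathogen response, rose from 32.2 ± 3.28 to 1117 ± 116, with 3367 ± 305 in N2. W09H1.4 (WBGene00012374) rose from 19.8 ± 4.42 to 351 ± 19.9, K08D12.4 from 1.33 ± 0.417 to 42.1 ± 2.83 and F10E9.2 from 4.0 ± 0.531 to 71.6 ± 23.3. Other genes lost small RNA that is scarcer in N2 worms: cnp-2 (WBGene00012901) fell from 314 ± 67.2 to 11.3 ± 6.65 CPM, with 0.669 ± 0.143 in N2, tbc-8, a Rab GTPase activator gene, fell from 168 ± 55.2 to 21.4 ± 3.08, with 5.69 ± 4.09 in N2, and haf-9, an ABC transporter gene, from 127 ± 37.5 to 23.9 ± 5.22, with 12.1 ± 4.79 in N2. Log2 fold changes among these ran from -4.83 ± 0.364 (SE) for cnp-2 to 6.33 ± 0.281 for rcan-1, with edgeR adjusted p of 0.00301 or less.

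**Figure D2:**
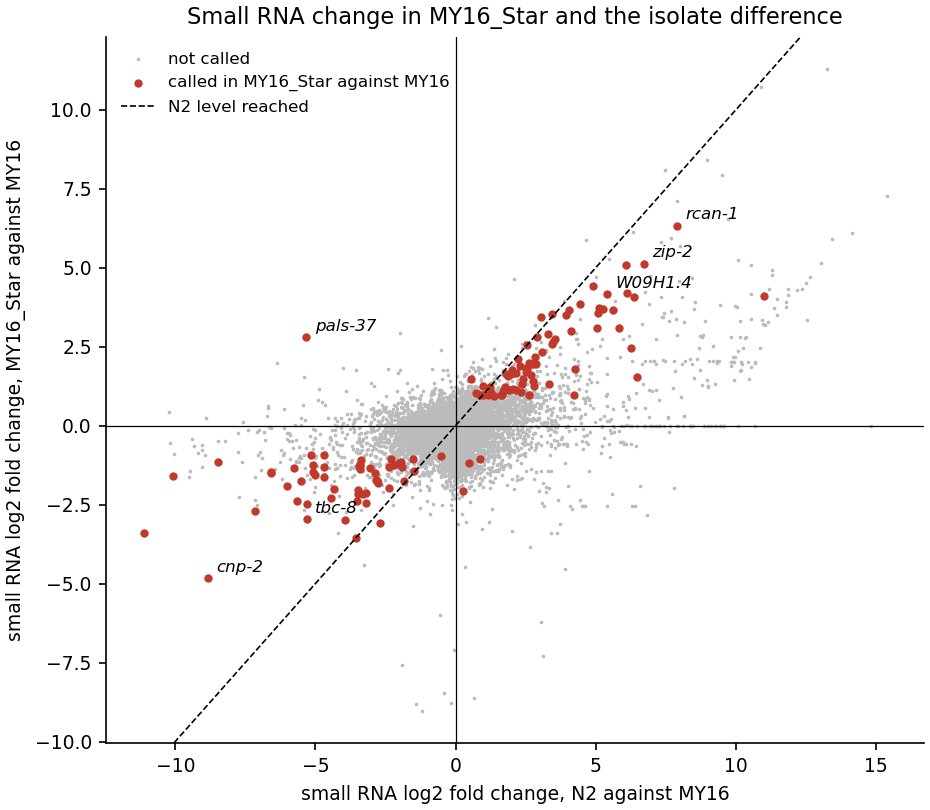
Small RNA log2 fold change per gene of MY16_Star against MY16 (vertical) by that of N2 against MY16 (horizontal); red points are the 125 genes called in MY16_Star against MY16, and on the dashed line MY16_Star would equal N2. Of the red points, 121 lie on the N2 side.

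In this comparison 70 genes were higher and 55 lower in MY16_Star among 12241 tested, and 121 of the 125 (96.8%) moved toward the N2 level. Of these 120 were also called between MY16 and N2: 68 rose where N2 is higher, against 7.0 for independent lists, and 52 fell where N2 is lower, against 4.7. Because both comparisons use the MY16 libraries, part of such an overlap may come from shared controls; 20 simulations of unchanged MY16_Star libraries gave at most 1 gene called in both toward N2, and 72.1% (65.6% to 79.2%) on the N2 side among the 125 genes with the smallest p. The covariance of the log2 fold changes was 0.609 against a simulated 0.185, a difference of 0.424, and r was 0.46 against 0.182. The genes that rose reached a median of 49.3% of the way to N2 in CPM, and those that fell 77.8%. On the log2 scale the order was the opposite, with median positions of 0.727 and 0.493. Of the 120, 107 have a location, with 26 on I, 12 on II, 24 on III, 18 on IV, 23 on V and 4 on X, or 1.24%, 0.601%, 1.23%, 0.855%, 1.22% and 0.327% of the genes tested there. The exceptions include pals-37, a gene of the pals family, which rose from 12.4 ± 2.86 to 89.1 ± 24.2 CPM (SD, n = 3) with 0.606 ± 0.603 in N2 (edgeR adjusted p 0.000818).

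Among the fixed lists, 4 of 180 F-box genes were higher and 1 lower in MY16_Star small RNA, with the same counts adjusted over the list alone. WAGO and heritable silencing targets were higher at 2 of 12 (3 adjusted over the list alone; camera adjusted p 0.00154, and adjusted p = 0.82 with an estimated correlation). The 2 genes, WBGene00017186 and WBGene00021107, had near-equal means, 62.0 and 66.0 CPM in MY16 and 144 and 141 in MY16_Star. They may share reads, so they may not be separate signals. Spermatogenesis genes had a median log2 fold change of -0.95 with 1 of 64 called lower (camera adjusted p 7.34e-06, and adjusted p = 0.959 with an estimated correlation), and C-type lectins one of -0.32 with 1 of 55 called lower, or 2 adjusted over the list alone (camera adjusted p 0.00159, and adjusted p = 0.82 with an estimated correlation). Without MY16 replicate 3 these 3 lists had a camera adjusted p of 0.0835, and the spermatogenesis median was -0.43. The detoxification list had 2 lower genes of 69. Neither hrde-1 nor prg-1 differed at the threshold, with small RNA of 636 ± 20.3 against 557 ± 73.7 CPM and 602 ± 87.9 against 574 ± 136 (SD, n = 3). The count of 125 became 80, 74 and 81 without MY16_Star replicate 1, 2 or 3 and 67 without MY16 replicate 2. With the replicate number as a block in a fit of these groups alone it was 188, of which 110 were among the 125.

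**Figure D3:**
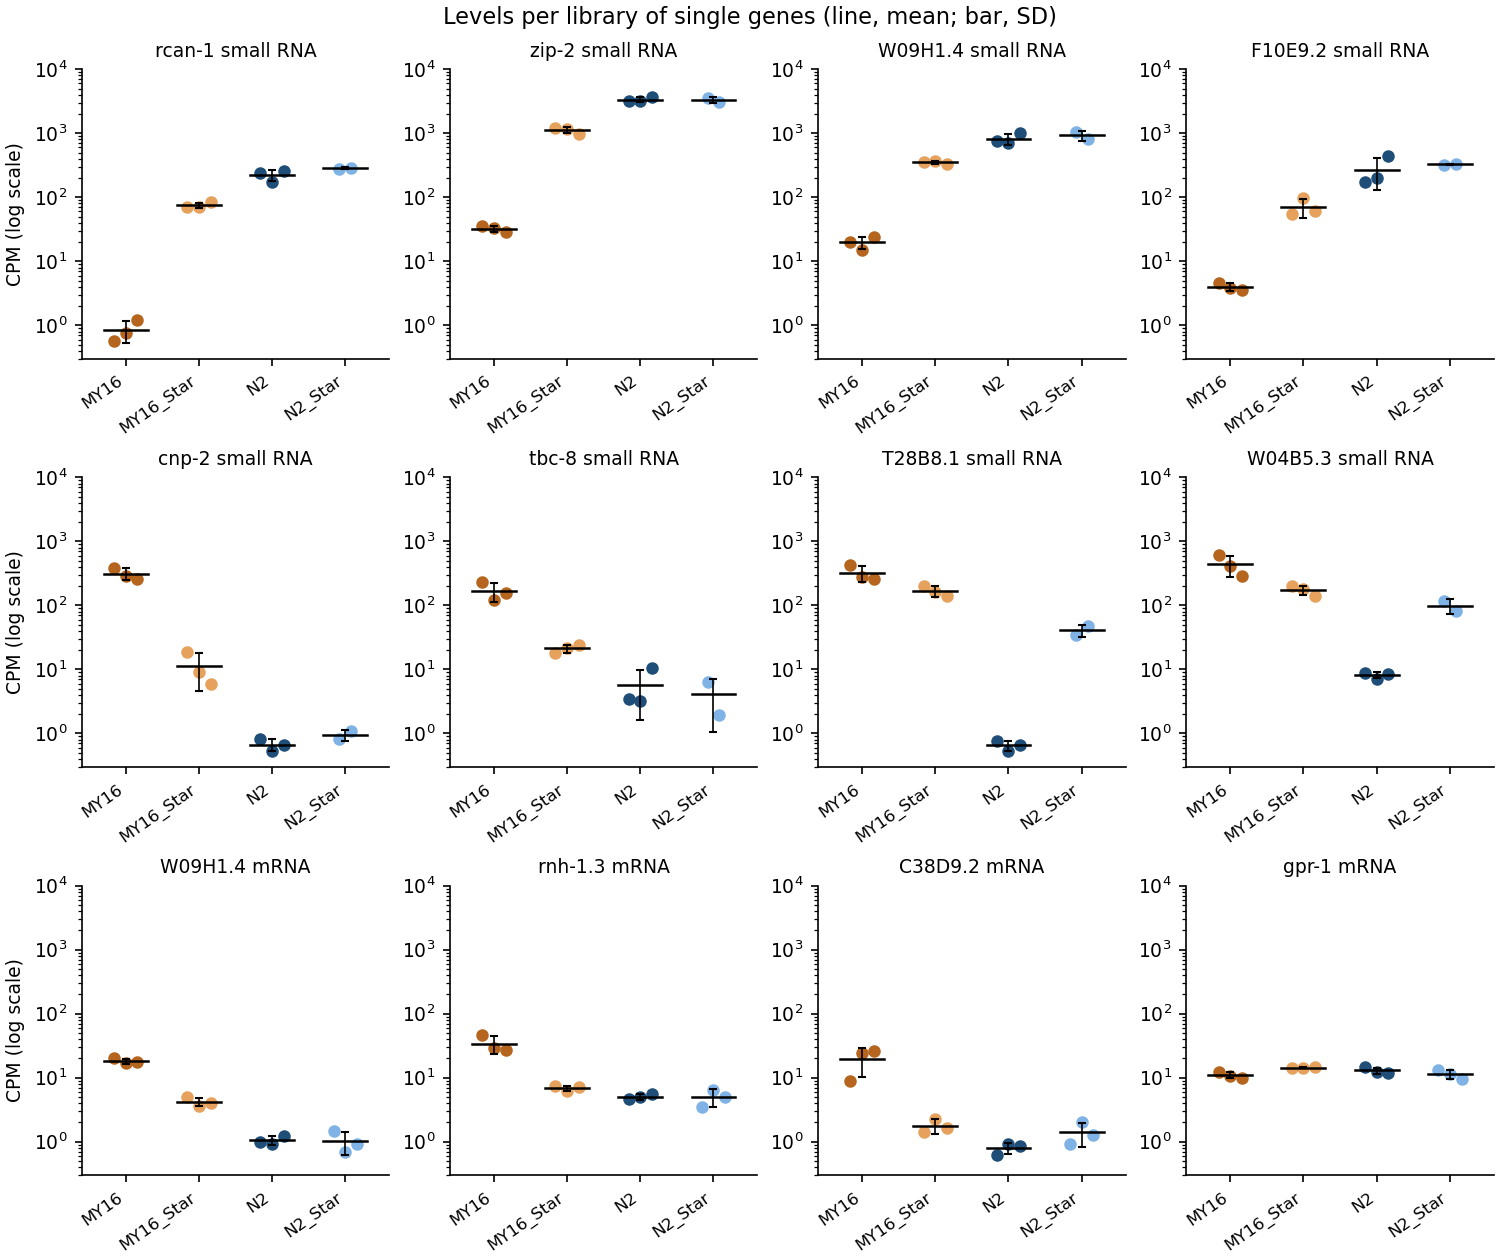
CPM per library (points, log axis), group mean (line) and SD (bar) for 8 genes in small RNA and 4 in mRNA over the 4 groups. In small RNA, rcan-1, zip-2, W09H1.4 and F10E9.2 lie higher, and cnp-2 and tbc-8 lower, in MY16_Star than in MY16; T28B8.1 and W04B5.3 lie higher in N2_Star than in N2.

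In mRNA, MY16_Star and MY16 differed at 3 genes, all lower in MY16_Star and all lower in N2 as well. All 3 were also called between the isolates, against 0.0515 for independent lists and at most 1 in 20 simulations of unchanged MY16_Star libraries. Part of the agreement in direction may come from the shared MY16 libraries, since the simulations put 86.7% (66.7% to 100%) of the 3 genes with the smallest p on the N2 side. The covariance over all genes was 0.00286, against a simulated 0.107. W09H1.4 (chromosome II, 13183528 to 13185914 in ce11) fell from 18.2 ± 1.72 to 4.23 ± 0.666 CPM, with 1.04 ± 0.167 in N2 (SD, n = 3). The RNase H gene rnh-1.3 (WBGene00007303) fell from 33.9 ± 10.3 to 6.86 ± 0.654, with 5.05 ± 0.518 in N2, and C38D9.2 (WBGene00008010), a heritable silencing target, from 19.6 ± 9.45 to 1.77 ± 0.466, with 0.792 ± 0.147 in N2. Small RNA of W09H1.4 and of rnh-1.3 rose in the same group, measured in other libraries than the mRNA. That of rnh-1.3, named for small RNA after its values were seen, went from 225 ± 34.4 to 1121 ± 261 CPM. Small RNA of C38D9.2 was 1238 ± 256 against 675 ± 515 CPM, with an edgeR adjusted p of 0.615. The 3 mRNA changes each had an edgeR adjusted p of 0.0237. The count was 0 without any of MY16_Star replicates 1, 2 and 3, MY16 replicates 2 and 3 or N2 replicates 2 and 3, 1 without MY16 replicate 1, and 0 in a fit of these groups alone; 619 genes had an unadjusted p under 0.05, and DESeq2 called 3.

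The 60 genes whose small RNA was higher in MY16_Star and whose mRNA could be tested lay lower in mRNA as a set: 44 of the 60, including W09H1.4 and rnh-1.3, had a negative log2 fold change, with a median of -0.26. Camera gave p = 0.00372 with an estimated correlation, and p = 0.0144 without the 2 genes called in mRNA. Among 50 genes with lower small RNA, 33 had a negative log2 fold change and p was 0.523. Of the fixed lists, all 40 oocyte and maternal germline genes were above 0 in MY16_Star against MY16, with a median of 0.35, but 0 were called by edgeR (camera adjusted p 7.32e-21, and adjusted p = 0.259 with an estimated correlation). Spermatogenesis genes had a median of -0.88 and body wall muscle genes one of -0.40, with camera adjusted p of 7.76e-13 and 5.69e-06; with an estimated correlation these were adjusted p = 0.436 and adjusted p = 0.259. Single libraries moved these medians: without MY16_Star replicate 1 the oocyte, spermatogenesis and body wall muscle lists had 0.21, -0.52 and -0.25. The latter 2 had -0.55 and -0.22 without MY16 replicate 3, spermatogenesis had -1.55 without MY16_Star replicate 3, and body wall muscle had -0.26 without MY16_Star replicate 2. Ribosomal proteins, heat shock genes, spindle genes, vitellogenins and histones lay above 0, and collagens, neurons and WAGO targets below it. Their camera adjusted p lay between 2.16e-07 and 0.00473, and none was under 0.05 with an estimated correlation, the lowest being adjusted p = 0.147 for WAGO targets. The calls of ribosomal proteins and histones ended without MY16_Star replicate 1 (0.628 and 0.16), that of histones also without MY16_Star replicate 2 (0.0786). Those of vitellogenins and heat shock genes ended without MY16 replicate 1 (0.135 and 0.157), that of heat shock genes also without MY16_Star replicate 3 (0.088), and that of collagens without MY16 replicate 3 (0.154).

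N2_Star worms carried more small RNA than N2 worms at 3 genes, each of which has abundant small RNA in MY16. All 3 were also called between the isolates, against 0.257 for independent lists and at most 1 in 20 simulations of unchanged N2_Star libraries. Part of the agreement in direction may come from the shared N2 libraries, since the simulations put 60% (33.3% to 100%) of the 3 genes with the smallest p on the MY16 side. The covariance over all genes was 0.126, as in the simulations (0.126). T28B8.1 (WBGene00012113, chromosome I, 8134115 to 8135051 in ce11) rose from 0.649 ± 0.112 CPM in N2 (SD, n = 3) to 41 ± 8.8 in N2_Star (n = 2), with 321 ± 89.7 in MY16. W04B5.3 (WBGene00021020) rose from 8.21 ± 0.908 to 99.8 ± 26.8, with 440 ± 161 in MY16, and T20B3.1 (WBGene00011850) from 6.59 ± 2.21 to 33.6 ± 0.947, with 389.9 ± 62.9 in MY16. Their edgeR adjusted p were 1.92e-05, 0.000914 and 0.00392. No gene was lower, 332 had an unadjusted p under 0.05, and DESeq2 called 14. Of the fixed lists 0 members were called; vitellogenins, ribosomal proteins and intestine lay above 0 and spermatogenesis genes below it, with camera adjusted p of 0.000498, 0.000473, 0.0153 and 0.0226, each with adjusted p = 0.675 with an estimated correlation. With library totals the spermatogenesis list had 0.0707, and all 4 list calls ended without N2 replicate 1 or 2. The count was 15 without N2 replicate 3, and 19 without the shallow libraries MY16 replicate 1 and N2 replicate 3. The call of T20B3.1 ended without N2 replicate 1 or 2. Fits without an N2_Star library leave 1 in that group and take the spread from the other groups, so their counts are not read here.

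In mRNA, 17 genes were higher and 4 lower in N2_Star than in N2. C10C6.7 (WBGene00007515) rose from 1.57 ± 0.227 to 12.3 ± 3.45 CPM and C55C3.3 (WBGene00016953) from 5.04 ± 0.414 to 21.2 ± 4.57 (SD, n = 3). The chitinase gene cht-1 rose from 22.4 ± 5.76 to 72.6 ± 14.1, and kpc-1, which encodes a furin-like proprotein convertase, from 25.3 ± 5.14 to 63.8 ± 14.5. Among the lower genes sax-2, a gene of neurite formation, fell from 192 ± 8.36 to 69.2 ± 19.9 CPM. With edgeR the adjusted p of these genes lay between 0.0123 and 0.035. Of the pals and pathogen response genes 0 of 23 were called by edgeR over all genes and 5 were higher adjusted over the list alone, with a median log2 fold change of 0.85 (camera adjusted p 4.41e-05, and adjusted p = 0.674 with an estimated correlation). Without N2_Star replicate 1 this median was 0.11, with a camera adjusted p of 0.693, and without N2_Star replicate 2 it was 1.34. Oocyte and maternal germline genes had a median of -0.31, the opposite sign to that in MY16_Star (camera adjusted p 1.83e-10, and adjusted p = 0.674 with an estimated correlation), and of -0.16 without N2_Star replicate 1 (camera adjusted p 0.00415) and -0.20 without N2 replicate 1. Early embryo, F-box and vitellogenin lists lay above 0, and spermatogenesis, RNAi cofactors and Argonautes below it, with camera adjusted p between 0.00317 and 0.0362; with an estimated correlation all had adjusted p of 0.674 or more. Each of these 6 calls ended without N2_Star replicate 1 or 2, and the spermatogenesis median turned from -0.21 to 0.09 without N2_Star replicate 1. Of the 21 genes 6 were also called between the isolates on the MY16 side, 3 higher and 3 lower, and 1 on the other side. Independent lists would share 0.292 and 0.0924. The 20 simulations of unchanged N2_Star libraries, which share the N2 libraries, gave at most 1. Of all 21, 71.4% lay on the MY16 side, against 83.1% (66.7% to 100%) of the top genes of the simulations, and the covariance over all genes was 0.0817 against 0.0998.

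The mRNA count of N2_Star against N2 depended on the libraries and the fit. It was 0 without N2 replicate 1, 2 or 3, 8 and 9 without MY16_Star replicate 2 or 3, 11 and 6 without MY16 replicate 2 or 3, and 177, 50 and 33 without N2_Star replicate 1, 2 or 3. DESeq2 called 364 genes, and a fit of these groups alone called 0, with 1698 genes at an unadjusted edgeR p under 0.05.

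Between the Star groups, mRNA of the oocyte and maternal germline list was higher and that of sperm genes lower in MY16_Star. Of 40 oocyte genes 28 rose and none fell (36 adjusted over the list alone), such as puf-7, a Pumilio RNA-binding protein gene, from 38.8 ± 7.97 in N2_Star to 86.0 ± 12.7 CPM in MY16_Star, and egg-3, a gene of egg activation, from 177 ± 19.5 to 307 ± 50.3 (SD, n = 3; edgeR adjusted p 0.00288 and 0.00561). Of 75 spermatogenesis genes 39 fell and 1 rose (54 and 1 adjusted over the list alone). Camera gave these lists adjusted p of 6.16e-15 and 1.84e-09, and adjusted p = 0.442 and adjusted p = 0.681 with an estimated correlation. The mean log2 CPM of the oocyte list was 9.10 ± 0.182 in MY16_Star, 8.77 ± 0.124 in MY16, 8.73 ± 0.117 in N2 and 8.41 ± 0.317 in N2_Star. The Star groups differed by 0.689 with an exact two-sided permutation p of 0.1, the smallest possible. Replicate 1 of N2_Star had the lowest score, 8.06, and without it the difference was 0.513.

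Other lists held called genes between the Star worms as well, where 2070 of all 13983 genes tested were lower and 1075 higher. MATH and BTB genes were lower in 29 and higher in 6 of 61 (30 and 8 adjusted over the list alone; camera adjusted p 1.52e-10, and adjusted p = 0.15 with an estimated correlation), and replicative histones higher in 10 and lower in 2 of 29 (13 and 2 alone; camera adjusted p 0.00026, and adjusted p = 0.442 with an estimated correlation). Collagens fell in 19 of 131 and rose in 2 (18 and 2 alone), with a camera adjusted p of 0.181. Their share of lower genes was near that of all genes. Among them dpy-3 stood at 0.338 ± 0.124 CPM in MY16_Star and 11.5 ± 15.6 in N2_Star (SD, n = 3). The level of dpy-3 is carried mostly by N2_Star replicate 1, without which its log2 fold change went from -5.05 to -2.85. Argonautes rose in 8 and fell in 3 of 20 (9 and 4 alone; camera adjusted p 0.0206, 0.159 without N2_Star replicate 1, and adjusted p = 0.697 with an estimated correlation). Among these prg-1 rose from 269.6 ± 17.9 to 444 ± 52.7 and sago-2 from 0.831 ± 0.261 to 4.08 ± 0.782, while sago-1 fell from 67.4 ± 4.94 to 36.6 ± 3.52 (edgeR adjusted p 0.00252, 0.000759 and 0.00404). The calls of hrde-1 and wago-1, both higher, ended in a fit of the Star groups alone, with edgeR adjusted p of 0.0677 and 0.0696. Of pals and pathogen response genes 6 of 23 fell and 1 rose (7 and 1 alone), including pals-27 from 2.22 ± 1.52 to 0.0216 ± 0.0374 CPM. The list had a camera adjusted p of 0.0399, 0.0911 with library totals and 0.0706 with the replicate number as a block. It had 0.118 without MY16_Star replicate 3, 0.558 without N2_Star replicate 1, and adjusted p = 0.726 with an estimated correlation. Ribosomal proteins had 0 called members, and their median of 0.08 turned to -0.07 with library totals, -0.06 without MY16_Star replicate 1 and -0.08 without N2_Star replicate 3.

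In all, 1075 genes were higher and 2070 lower in MY16_Star than in N2_Star by edgeR. With library totals in place of TMM the split was 582 and 2565, and the median log2 fold change of all genes moved from -0.12 to -0.26. The count of 3145 was 1281 without MY16_Star replicate 1, 1298 without MY16_Star replicate 2 and 1905 without N2_Star replicate 3, and 792 in a fit of the Star groups alone. A like fit of MY16 and N2 alone gave 687.

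Small RNA of many MATH and BTB, F-box and chemoreceptor genes was lower in MY16_Star than in N2_Star. That of bath-1 stood at 1.43 ± 0.538 CPM in MY16_Star (SD, n = 3) and 91.1 ± 2.19 in N2_Star (n = 2), that of btb-12, a BTB domain gene, at 0.0241 ± 0.0417 and 33.9 ± 1.86, and that of inx-16 at 94.7 ± 18.7 and 0.614 ± 0.0585. MATH and BTB genes were lower at 25 and higher at 4 of 55 (28 and 7 adjusted over the list alone; camera adjusted p 4.68e-15, and adjusted p = 0.0412 with an estimated correlation). F-box genes were lower at 61 and higher at 10 of 180 (75 and 15 alone; camera adjusted p 1.11e-09, and adjusted p = 0.335 with an estimated correlation), and chemoreceptors lower at 17 and higher at 5 of 62 (26 and 6 alone; camera adjusted p 0.00174, and adjusted p = 0.465 with an estimated correlation). Also lower were 9 of 79 ribosomal protein genes (6 alone), 14 of 53 histone genes (18 alone), 7 of 14 heat shock genes (9 alone) and 3 of 6 vitellogenins (5 alone), whose lists had camera adjusted p between 0.00337 and 0.0218 (histones 0.0638 without MY16_Star replicate 3), and adjusted p = 0.672 with an estimated correlation. Small RNA of 4 of 21 Argonaute genes was higher, among them sago-2 at 50.2 ± 2.37 against 22.5 ± 3.1 CPM. With only 2 N2_Star libraries, how far this call rests on either of them cannot be told. By edgeR 713 genes were higher and 1060 lower. The total of 1773 was 1121 without MY16_Star replicate 2, and 2818 without the shallow libraries MY16 replicate 1 and N2 replicate 3. Fits without an N2_Star library leave 1 in that group, so their counts are not read here.

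The Star difference itself differed between the isolates at 45 small RNA genes, 21 with a higher and 24 with a lower difference in MY16. Small RNA of rcan-1, zip-2 and W09H1.4 rose in MY16_Star, while N2_Star stood at 286 ± 7.14, 3350 ± 371 and 928 ± 163 CPM (SD, n = 2), near the N2 means; the log2 interaction values were 5.97 ± 0.361 (SE), 5.13 ± 0.320 and 3.98 ± 0.345. T28B8.1, W04B5.3 and T20B3.1, which rose in N2_Star, had values of -6.89 ± 0.416, -4.95 ± 0.417 and -4.41 ± 0.344. The edgeR adjusted p of these 6 genes was 0.000207 or less. The count of 45 was 28 without MY16_Star replicate 2 or MY16 replicate 2, 26, 23 and 80 without N2 replicate 1, 2 or 3, and 91 without the shallow libraries. Fits without an N2_Star library leave 1 in that small RNA group, so their counts are not read here. In mRNA 0 genes were called by edgeR, with 1830 at an unadjusted p under 0.05, and DESeq2 called 83; the edgeR count was 1 without MY16 replicate 1 and 8 without N2_Star replicate 1.

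Over the 1420 to 1588 genes used for this position, MY16_Star small RNA lay nearer to N2 than MY16 small RNA did. On the line from MY16 (0) to N2 (1), MY16_Star libraries averaged 0.238 ± 0.0558 and MY16 libraries 0.065 ± 0.0175 (SD, n = 3 each), a difference of 0.173 with an exact two-sided permutation p of 0.1, the smallest possible. In mRNA MY16_Star averaged -0.0225 ± 0.141 and MY16 0.206 ± 0.0799, a difference of -0.228 away from N2 (exact p 0.1), which was -0.00193 without MY16 replicate 1. N2_Star small RNA averaged 0.0482 ± 0.00157 (n = 2) and N2 0.0589 ± 0.0238 (n = 3) on the line from N2 to MY16 (exact p 1), and the difference of -0.0107 turned to 0.0283 without N2 replicate 3. In mRNA N2_Star averaged 0.134 ± 0.181 and N2 0.0894 ± 0.056 (n = 3 each; exact p 0.9), and the difference of 0.0448 turned to -0.0315, -0.0400 and -0.0457 without MY16 replicate 1, N2 replicate 2 or N2_Star replicate 1. The Star differences of the isolates, which share no libraries, correlated across genes with r = 0.0924 in small RNA and -0.0993 in mRNA. The latter was -0.223 over genes with a mean log2 CPM over 5. No gene was called in both Star differences in the same direction. Independent lists would share only 0.0172 higher genes in small RNA and 0.000858 lower genes in mRNA, so this absence says little. Small RNA of W04B5.3 and T20B3.1, higher in N2_Star, was called lower in MY16_Star, with log2 fold changes of -1.33 and -1.91.

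**Figure D4:**
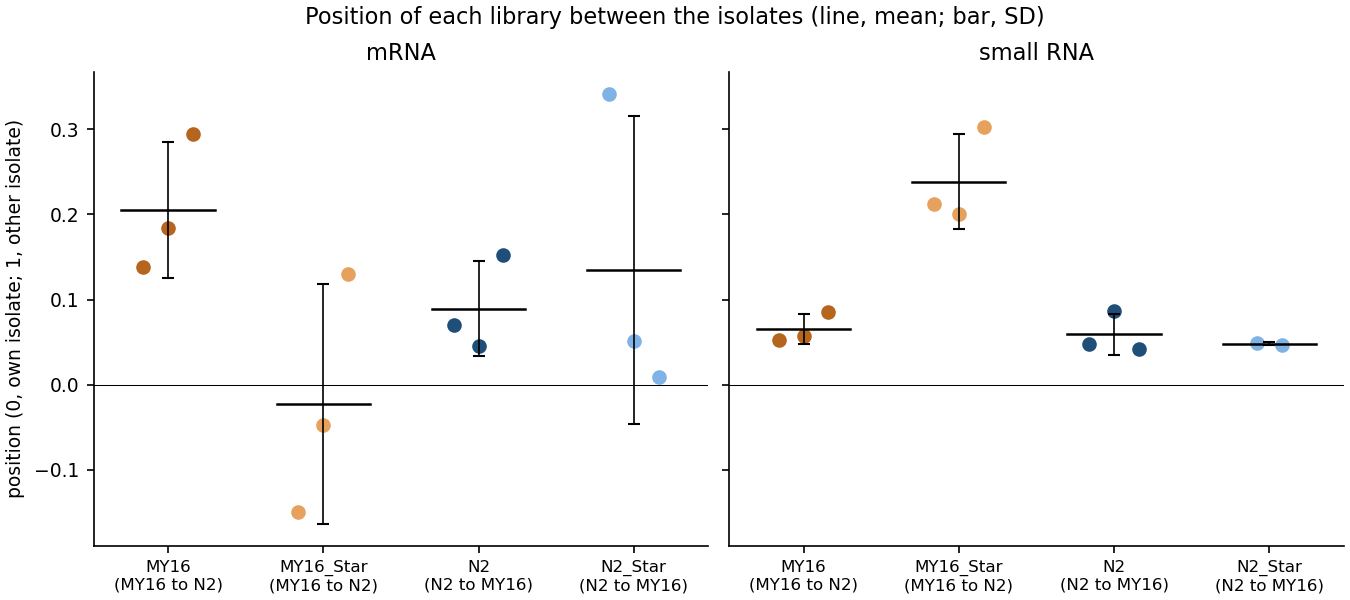
Position of each library (points) on the line from its own isolate (0) to the other isolate (1) for mRNA and small RNA, with group means. MY16_Star small RNA libraries lie between 0.201 and 0.303, above the MY16 libraries, which lie between 0.0526 and 0.0850.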

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

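The test for mixed-in N2 material below was chosen only after the result was seen, and the other tests of this part were fixed before it.

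Small RNA differences between Star and isolate were unlike in MY16 and N2 at 45 genes by the edgeR interaction test. The interaction, in log2 units, was 5.97 for rcan-1, 5.13 for zip-2, 4.80 for K08D12.4, 4.48 for F22B7.9, 4.20 for ZK856.4, 4.04 for afmd-2, an arylformamidase gene, 3.98 for W09H1.4, 3.96 for F26D11.1, 3.93 for F10E9.2 and 3.86 for F09G2.1. It was -3.07 for C55C3.3, -3.15 for nlp-40, a neuropeptide gene, -3.42 for elmd-1, -3.47 for C53D5.5, -3.61 for spds-1, a spermidine synthase gene, -4.41 for T20B3.1, -4.95 for W04B5.3, -5.27 for cnp-2 and -6.89 for T28B8.1.

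Gene lists also moved unlike in the isolates by camera on the interaction with a preset correlation. In mRNA the lists higher in MY16 than in N2 on this contrast were oocyte and maternal germline (adjusted p 1.2e-23), Argonautes (0.00928), RNAi cofactors (0.00803, with a median that turned to -0.01 under library totals), spindle pulling force (0.00325) and heat shock (0.00325). The lower ones were spermatogenesis (0.0375), collagens (0.00122), body wall muscle (0.0171), neurons (0.00885), WAGO targets (0.0406), F-box genes (0.0443) and pals genes (0.000589). Under library totals spermatogenesis had 0.136 and F-box genes 0.135. In small RNA they were spermatogenesis (0.0244) and C-type lectins (0.0119), both lower, and WAGO targets (0.019), higher. Without N2_Star replicate 1 or MY16 replicate 3 each of these calls ended, except those of oocyte, spindle and neuron genes, which were kept as any single library was left out. None passed with an estimated correlation, the lowest being adjusted p = 0.322 in mRNA and adjusted p = 0.892 in small RNA.

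The first pattern is that 121 of the 125 small RNA changes of MY16_Star against MY16 lie on the N2 side, with rcan-1, zip-2 and W09H1.4 among the largest. N2 worms or RNA mixed into MY16_Star would raise every gene whose small RNA marks N2 by about 1 share, but the median share of the N2 level over 171 such genes was 0.957%, with 119 of them under 5%. Genes called lower lost a median of 77.8% of their distance to N2 in CPM, but a large loss follows from that choice. The 130 genes that mark MY16, chosen without MY16_Star, lost a median of 55.5%, with quartiles of 29.5% and 66.7%. N2 chromosome segments would bring N2 mRNA levels to genes near the moved ones, but the median position of 91 such genes within 100 kb was 0, with quartiles of -0.0536 and 0.107, and the MY16 libraries shared by both comparisons gave at most 1 gene in 20 simulations against 120. A small RNA difference carried by whatever Star marks stays open as a candidate explanation and was not tested apart from the group itself. The preparation of the Star worms is not stated in the labels, so a difference in handling or growth of the groups stays open as well.

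The second pattern is that more mRNA genes were called between the Star groups (3145) than between MY16 and N2 (563) in the fit of all groups, with oocyte genes such as puf-7 higher in MY16_Star. Sperm genes were lower, with a list median of -1.70, but had one of -1.10 between the isolates already (-0.72 without MY16 replicate 1). The excess depends on the fit: with each pair fitted alone the counts were 792 and 687, which leaves little of it. Without MY16_Star replicate 1 or 2 or N2_Star replicate 3 it was smaller in the fit of all groups, at 1281 against 581, 1298 against 515 and 1905 against 551 genes. N2_Star replicate 1 stands apart from the other libraries, but without it the Star groups differed at 3631 genes and MY16 and N2 at 809 in the same fit. A difference in germline content between libraries was examined across genes outside the oocyte list. The slope on the list score within groups correlated with the interaction at r = 0.192 and with the difference between the Star groups at r = 0.067. The first value lies just under the limit set in advance as counting against this cause. As single libraries were left out it ran from 0.152 to 0.386, across that limit, so the test leaves the question undecided. The Star state of the worms, which the design names, stays open and untested.

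The third pattern concerns mRNA of the genes whose small RNA changed in MY16_Star. Where small RNA was higher, as at W09H1.4 and rnh-1.3, mRNA lay lower as a set, with camera p = 0.00372 using an estimated correlation, which is consistent with small RNA that lowers mRNA of its genes. Among the 110 genes called in small RNA rho of the 2 assays was -0.184, but over all 9864 genes it was 0.215, so the reading holds at most for the called genes. Where small RNA was lower, as at cnp-2 and tbc-8, mRNA leaned lower as well, with 33 of 50 genes negative, a median of -0.14 and a camera p of 0.523. The test set in advance for higher mRNA at these genes asked for a higher direction with p under 0.05, and neither was met. Both sets thus leaned lower in mRNA, so the lower mRNA of the first set is not matched by a rise in the second. A p above the threshold does not exclude a rise at single genes. The first set has a mean difference of its score of -0.368 with an exact permutation p of 0.1, the smallest possible for 3 against 3 libraries. A lower mRNA level that came first, with small RNA following it, would give the same values and was not tested.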

How the results depend on the processing

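The alternatives without the shallow small RNA libraries, with a block in a fit of 2 groups and, for gene lists, without single libraries were chosen only after the data were seen; the others were planned. Of 236 named gene results, 165 kept their side of the threshold under every alternative run; of 203 calls, 135 were kept under all and 68 lost under at least 1, and 0 changed direction. Counts for MY16 against N2 stayed within 1.5 times under every alternative, at 404 to 809 in mRNA and 1598 to 2238 in small RNA as single libraries were left out, against 563 and 2271. Without a filter, small RNA of MY16_Star against MY16 gave 522 calls, N2_Star against N2 123 and the interaction 282, and mRNA of N2_Star against N2 233 and the interaction 5. DESeq2 gave 273, 14 and 129 in small RNA and 364 and 83 in mRNA for the same comparisons. Fits of the compared groups alone gave 0 for mRNA MY16_Star against MY16, 0 for N2_Star against N2 and 792 for MY16_Star against N2_Star, from fewer libraries to estimate the spread. Without the shallow libraries small RNA gave 19 for N2_Star against N2, 2818 for the Star groups and 91 for the interaction. In the small RNA values that follow, a fit without an N2_Star library leaves 1 in that group and takes the spread from the other groups. As single libraries were left out, mRNA counts ran from 0 to 3 (MY16_Star against MY16), 0 to 177 (N2_Star against N2), 1281 to 3631 (Star groups) and 0 to 8 (interaction), and small RNA counts from 67 to 151, 2 to 15, 1010 to 2182 and 20 to 80. The cause was not tested for the changes under no filter and DESeq2. Of 68 list calls, 26 were kept as single libraries were left out and 42 ended without at least 1; without N2_Star replicate 1 the direction of the spermatogenesis list in N2_Star against N2 turned in mRNA (adjusted p 0.878) and small RNA (0.953), and without N2_Star replicate 3 that of ribosomal proteins between the Star groups (0.999). As single libraries were left out, the adjusted p of these 3 lists ran from 9.57e-06 to 0.878, from 5.13e-06 to 0.953 and from 0.000297 to 0.999.

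The position of N2_Star changed sign in mRNA from 0.0448 to -0.0315 without MY16 replicate 1, -0.0400 without N2 replicate 2 and -0.0457 without N2_Star replicate 1, and in small RNA from -0.0107 to 0.0332 over genes with a mean log2 CPM over 5 and 0.0283 without N2 replicate 3; left-out libraries gave -0.0457 to 0.118 and -0.0350 to 0.0283. That of MY16_Star kept its sign, at -0.254 to -0.00193 in mRNA and 0.131 to 0.193 in small RNA. The correlation of the Star differences in mRNA moved from -0.0993 to -0.223 over genes with a mean log2 CPM over 5; the cause was not tested. With the replicate number as a block, MY16_Star against MY16 small RNA, the comparison whose libraries pair, gave 113 calls, 101 of them among the 125, and 188 in a fit of those groups alone; of the named genes it ended the calls of zip-7, ugt-64, gst-37 and clec-75, and it changed no list call there. Elsewhere the numbers were not taken to pair the libraries, since not every same-numbered pair correlated above 0.1. In mRNA 12 of 18 pairs did, all those of replicates 1 and 3 and none of replicate 2, with a median of 0.17 against -0.0855 for other pairs. Deviations in a group of 3 sum to 0, so replicate 2 lies near 0 where replicates 1 and 3 lie apart, and the rule is hard to meet. As a further hint, 8 of 12 mRNA and 6 of 11 small RNA libraries correlated best with their own number. A batch shared by same-numbered mRNA libraries is thus possible, and the main tests leave it out. The block gave 109 calls for mRNA N2_Star against N2 and 1 for the mRNA interaction. It moved mRNA list calls both ways: pals genes between the Star groups ended (camera adjusted p 0.0706), and ribosomal proteins passed in the interaction (0.0446). Depth limits small RNA most in MY16 replicate 1 and N2 replicate 3, where 3 counts equal 1.72 and 1.95 CPM.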

Other observations

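The levels of genes that mark an isolate and the division of the 94 genes, below, were compared only after the data were seen, and the other tests of this part were fixed before their results.

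Genes whose small RNA marks MY16 lost a large part of it in MY16_Star, well beyond the called ones. Over 130 genes with at least 20 CPM in MY16 and at least 8 times the N2 level, MY16_Star libraries stood at a median of 47.2% ± 3.93 of the MY16 level (SD, n = 3), against 93.1% ± 18 for MY16 libraries left out of the choice, a difference of -45.9 percentage points with an exact two-sided permutation p of 0.1, the smallest possible. Of these genes 117 lay below and 34 were called lower, among them cnp-2 and T20B3.1. Genes that mark N2 stood at 105% (95.3% to 115%, n = 2) in N2_Star and 94.7% in left-out N2 libraries, with an exact permutation p of 0.6. Gain in MY16_Star was uneven by comparison, since the 171 genes that mark N2 had quartiles of 0.305% and 6.99% of the N2 level.

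A hypothesis for this unevenness is that N2-like small RNA may appear only at genes that MY16 worms express. Among genes marking N2, the 45 with an MY16 mRNA mean of at least 1 CPM had a median share of 9.97% of the N2 small RNA level (quartiles 2.42% and 41.1%), with 23 called higher, zip-2 and W09H1.4 being of this kind. The 32 genes at 3 counts or fewer in every MY16 mRNA library and with an N2 mRNA mean of at least 1 CPM had 0.384% (0.308% and 0.67%) with 0 called by edgeR, and the other 94 had 0.605% with 6 called. Of these 94, 69 were at 3 counts or fewer in every MY16 library and under 1 CPM in N2, with a median of 0.465% and 2 called, plg-1 and ZK686.6, named after their values were seen. Small RNA of ZK686.6 rose by 3.08 ± 0.236 log2 units (SE), to 85.0 ± 5.52 CPM (SD, n = 3), which goes against the word only in the hypothesis; the call of plg-1 ended without MY16 replicate 1 or 3. The order of the medians is that of the hypothesis, but the first lies just under the 10% set for it in advance, so the test leaves it open. Genes that MY16 lacks altogether could yield no small RNA made by the worms themselves, which would also give low shares. This limit would not hold for small RNA received from other worms.

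Splits of the same libraries into other groups were counted with edgeR. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In mRNA, 1 of the 10 splits gave as many calls as the real one for MY16 against N2 (563, highest other 0), N2_Star against N2 (21, highest other 0) and the Star groups (3145, highest other 2), and 2 did for MY16_Star against MY16 (3, highest other 316). The split with 316 calls put MY16 replicates 2 and 3 with MY16_Star replicate 3, which points to a structure of these samples other than their groups. It set replicate 1 of both groups apart from replicate 3 of both groups, as a batch by replicate number would. In small RNA 1 split gave as many for MY16 against N2 (2271, highest other 1) and for MY16_Star against MY16 (125, highest other 0). For the mRNA interaction the real edgeR count is 0 (1830 genes at an unadjusted p under 0.05, 83 by DESeq2), so each of the 40 splits drawn gives as many by construction, the highest other being 1, and they say nothing about chance.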
